A study of Mus musculus with 10 samples.

How the data were processed

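RNA-seq libraries from mouse platelets of 2 ages were compared, 5 from mice labelled P7, read here as postnatal day 7, and 5 from adult mice, each with a replicate letter (A, B, C, E and I at P7, and A, B, C, G and H in adults). Per the labels' protocols, RNA was isolated with Trizol and cDNA was made and amplified from 1 ng of total RNA by SMARTer chemistry for low input. Of this, 150 pg of cDNA went into Nextera XT libraries, and single-end reads of 75 nt came from a NextSeq 550. The labels do not say whether libraries came from separate animals, pooled animals or repeated draws, so p-values measure the spread between these samples, which may be technical. Sex and strain are not given in the sources used here.

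The deposited values are raw counts of reads per gene symbol, whole numbers that sum to a different total in each library, and no normalization by the authors was seen in them. Per the submitters' processing notes, fastp 0.23.1, STAR 2.7.9a, Subread 2.0.1 with featureCounts, and Salmon 1.5.2 were used, with no role stated for each. The genome build is not given in the sources used here, so no coordinates are printed. Genes with near-identical copies, such as Hba-a1 and Hba-a2 or the class I genes of the H2 family, and genes that overlap on the chromosome can share reads, and their values are uncertain. The amplification has no molecular identifiers, so limits from counts cover counting error only.

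Each library held 53819 gene symbols and a total of 19431863 to 25029931 counts. A count of 0 allowed a level of up to 0.120 CPM in the deepest library and 0.154 CPM in the shallowest, taken as 3 counts of the total. A fold against a group with 0 counts in each library used 3 counts over the summed libraries of that group, 0.0279 CPM in adults. Genes were kept with edgeR's filterByExpr at its defaults (minimum count 10, minimum total 15), which left 8198. Counts were scaled with TMM factors and tested with edgeR's quasi-likelihood F test with robust dispersions (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with age group as the only term, and p-values were adjusted by Benjamini-Hochberg. A gene was called at an adjusted p under 0.05. Fold changes are P7 over adult, levels are TMM-scaled CPM unless stated otherwise, and SE is that of the log2 fold change.

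Before the data were examined, 28 gene lists were fixed, covering platelet functions, housekeeping processes and markers of other cell types. They were platelet identity, agonist receptors and signalling, alpha-granule cargo, granule biogenesis and secretion, cytoskeleton, MHC class I, interferon response and innate immune receptors. Further lists were fetal and neonatal growth, cell cycle, apoptosis, proteasome, autophagy, glycolysis, immediate early genes, ribosomal proteins, mitochondrially encoded proteins, nuclear oxidative phosphorylation and translation factors. Marker lists were those of erythroid, neutrophil, monocyte, B, T and NK, basophil, progenitor, endothelial and hepatocyte cells. Lists with at least 5 tested members, 25 of them, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Shares of counts, 11 measures in all, were compared with a two-sided exact permutation test over 252 splits, whose smallest p is 0.0079, adjusted by Benjamini-Hochberg. The list entries Hbb-b1, Hbb-b2, Ahsp, Vamp7, Zac1 and Vps34 had no row under these symbols and were not used here.

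Named genes followed a rule fixed at the same time. It took up to 12 genes per direction with the largest fold change among called genes with a mean of at least 20 CPM and no overlap between the groups. It also took up to 4 called members of each list with the smallest p (or the 2 most abundant where none was called), and a fixed set of platelet, globin and sex-linked genes. Unnamed gene models, clones, pseudogenes and mitochondrially encoded genes were passed over in the ranking by fold change.

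The tests were also run on simulated data drawn from the gene means, dispersions and library sizes of these 10 libraries, with 200 genes changed. Among 7878 genes, edgeR recovered 4.92% of the genes changed 1.5-fold, 29.5% of those changed 2-fold and 79.4% of those changed 4-fold, and 6.58% of its calls were false. For DESeq2 19.0% of calls were false and for limma-voom 10.5%. A list moved on purpose was called by camera, and 0 of 20 lists left alone were. The simulated genes were drawn independently of each other, while correlations estimated in the data were 0.34 for ribosomal protein and 0.21 for cell cycle genes. The simulation therefore cannot show how often camera calls lists of correlated genes falsely. Recovery may also differ in the data, where 2272 genes were called.

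Alternatives were other scalings (RLE, library size only, upper quartile), DESeq2 1.42.0, limma-voom, and other filters and thresholds. They also covered removal of erythroid or mitochondrially encoded genes, marker levels as covariates, equal depth, each library left out, and the shared letters A to C as a block. A planned covariate, the ratio of Y-linked to Xist counts, could not be run because Xist had 0 counts in each of the 10 libraries. The level of Y-linked genes was used instead, and removal of a trend with GC content was added, both chosen after the data were seen. GC content came from GENCODE transcripts of another annotation than that of the files, with a value for 97.9% of tested genes, and the trend of each library was fitted with a spline of 5 degrees of freedom. A fit with libraries scaled to the summed counts of the platelet identity list, in place of TMM, was added after the results were seen. The test was also run on 100 splits of the 10 libraries into 5 and 5, drawn from 126 with the real one included. Within each group a library was listed as far from the others where its gap to the nearest, over the range of the 5, was above 0.71, Dixon's critical value.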

Results

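Platelet RNA from P7 mice was compared with platelet RNA from adult mice, with 5 libraries at each age. Platelets are anucleate blood cells that carry RNA from their parent megakaryocytes. Total counts per library ran from 19431863 to 25029931 at P7 and from 19541997 to 23291269 in adults (n = 5 each; two-sided exact permutation p = 0.35, adjusted 0.43), and 12454 to 14965 genes were detected per P7 library and 12270 to 13138 per adult library.

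B2m, the light chain of MHC class I, averaged 1250 ± 491 CPM at P7 and 5715 ± 1009 CPM in adults (SD, n = 5 each), and fell by 2.19 ± 0.22 on the log2 scale (SE). Log2 fold changes were -1.57 ± 0.25 for the chemokine precursor gene Ppbp, -1.34 ± 0.19 for the ADP receptor gene P2ry12 and -1.55 ± 0.28 for Selp, which encodes P-selectin (SE), and these genes also passed the test. Gp9, of the von Willebrand factor receptor, rose by 0.88 and the signalling adaptor Lat by 1.32. Pf4, which encodes another platelet chemokine, had a log2 fold change of 0.05 ± 0.14 (SE, adjusted p = 0.81 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Gp1ba one of 0.13 ± 0.16 (adjusted p = 0.60 in the same edgeR test).

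Of 8198 genes tested, 1132 were higher and 1140 lower at P7 in edgeR's quasi-likelihood test, together 27.7%, and 739 and 627 of these changed at least 2-fold. Among 2025 genes with a mean of at least 20 CPM, 604 (29.8%) had no overlap between the groups, where chance gives 0.794%. The first principal component held 41.3% of the variance and separated the ages. Correlations between libraries were 0.941 to 0.967 within a group and 0.898 to 0.930 between groups. With the erythroid marker level as a covariate, of whose variance age explained 82.1%, 29 genes were called, and 313 were called with the neutrophil marker level. With the erythroid covariate 17 of 124 named genes kept their call or lack of one. B2m, at -1.44 ± 0.42 (SE), did not pass (adjusted p = 0.16 in edgeR's quasi-likelihood test, the highest of 29 settings for this gene, whose lowest was 1.19e-17). With the neutrophil covariate B2m was at -3.07 ± 0.44 (SE) and passed (adjusted p = 0.00478 in the same test).

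**Figure D1:**
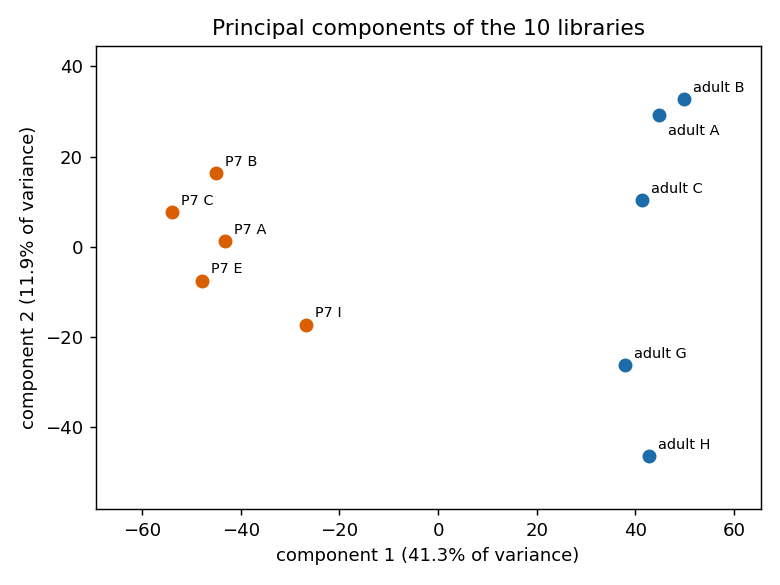
Principal components of log2 CPM, with each point a library, P7 in orange and adult in blue, and the share of variance on each axis. The 5 P7 libraries lie at component 1 scores of -53.8 to -26.7 and the 5 adult libraries at 37.8 to 49.8.

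Among genes with a mean of at least 20 CPM and no overlap between the groups, the largest increase was that of Ttc9, at 192 to 550 CPM in P7 A, B, C and I, 0.960 CPM in P7 E, and under 1 CPM in each adult library. The log2 fold change of Ttc9 was 9.98 ± 1.60 (SE) and 10.28 without P7 E. The log2 fold change of Ttc9 was 8.58 in limma-voom, 10.80 with the erythroid covariate and 9.96 with the neutrophil covariate, and did not pass in these fits (Benjamini-Hochberg adjusted p = 0.41, 0.15 and 0.12). Ajap1 followed at 6.21 ± 0.77, with the collectin gene Colec11 at 3.97 ± 0.33 and the collagen gene Col18a1 at 2.91 ± 0.43. Lgals9, which encodes galectin-9, rose by 2.50, the GTPase gene Rac2 by 2.39 and the tropomyosin gene Tpm2 by 2.34. Increases were smaller for the other genes of this set, with Ociad2 at 2.32, Ehd3 at 2.30, Ptp4a3 at 2.27, the actin-binding Cotl1 at 2.23 and Tarbp2 at 2.20. Tpm2 reached 1077 ± 361 CPM at P7 against 213 ± 68.2 CPM in adults (SD, n = 5 each).

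The largest decrease among such genes was that of Aldh1a1, a retinaldehyde dehydrogenase gene, with 1.71 ± 0.606 CPM at P7 and 59.0 ± 28.1 CPM in adults (SD, n = 5 each) and a log2 fold change of -5.11 ± 0.38 (SE). Log2 fold changes were -3.29 for Lrrn3, -3.28 for the cell cycle inhibitor gene Cdkn2b, -3.04 for Tm4sf19, -2.95 for the cytochrome oxidase subunit gene Cox5a and -2.82 for Mtmr1. They were -2.63 for the initiation factor gene Eif3h, -2.51 for Nabp1, -2.37 for Pla2g4a, the phospholipase gene whose product releases arachidonic acid, -2.36 for Pamr1, -2.30 for Triqk and -2.26 for Cldnd1. Adjusted p-values of these 24 genes in edgeR's quasi-likelihood test ran from 1.17e-06 for Cox5a to 0.0386 for Ociad2. The log2 fold change of Ociad2 lost its call without any 1 of P7 A, B, C, E and I and adult B, G and H, at 2.06 to 2.53. The log2 fold change of Pamr1 lost its call without any 1 of P7 A and E and the 5 adult libraries, at -2.41 to -2.18.

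**Figure D2:**
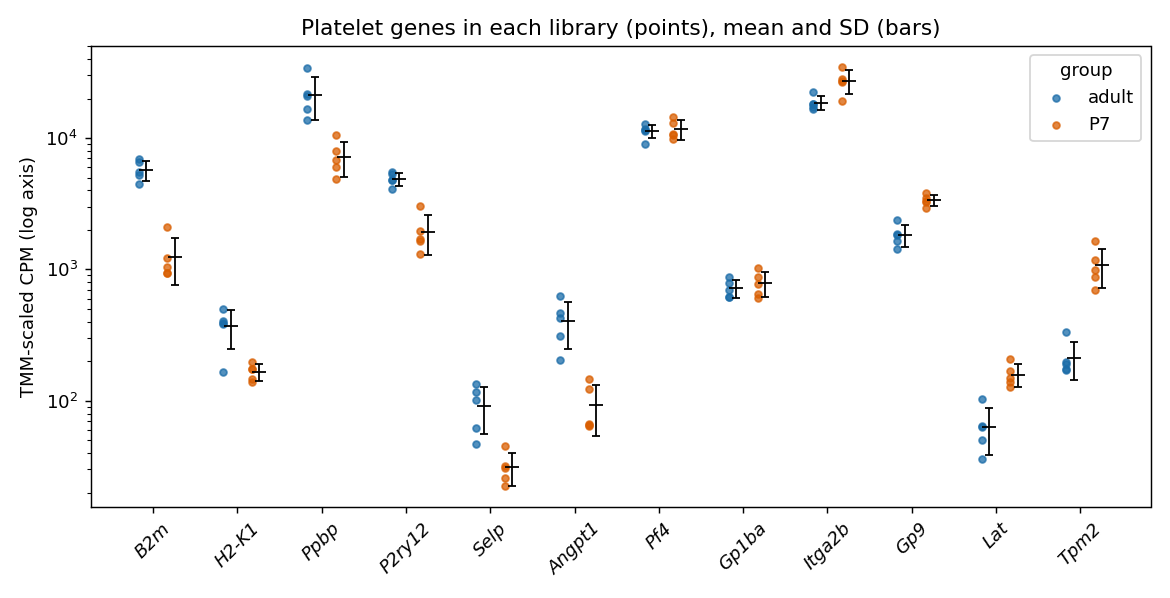
TMM-scaled CPM on a log axis for 12 platelet genes, with each point a library, adult in blue and P7 in orange, and black bars for the mean and SD of 5 libraries. B2m lies at 937 to 2103 CPM in P7 libraries and 4437 to 6921 CPM in adult libraries, while the Pf4 points of both ages overlap.

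Among genes of platelet function, the identity list had 7 higher and 7 lower of 30 tested (9 and 8 adjusted over the list alone), with Gp9 and Itga2b higher, at 0.88 and 0.55, and Ppbp, Selp and Cd9 lower, the last at -0.75. With the GC trend removed the log2 fold change of Itga2b was 0.24 and did not pass (adjusted p = 0.19 in edgeR's quasi-likelihood test). The agonist receptor list had 7 higher and 9 lower of 47 (7 and 10 adjusted over the list alone). In it the thrombin receptor gene F2rl3 rose by 1.26, and the log2 fold change of Rap1b, a GTPase gene of integrin activation, was -0.85. Of 18 alpha-granule cargo genes 5 were higher and 4 lower, also adjusted over the list alone, with Sparc at 2.30, Angpt1 at -2.12 and Il7 at -4.06. Of 26 genes of granule biogenesis and secretion 5 were higher and 4 lower (5 and 5 adjusted over the list alone), with Ap3b1 at 1.43 and Vamp8 at 1.02. The SNARE genes Vamp3 and Snap23 had log2 fold changes of -1.20 and -0.93. The platelet identity genes held 12.7 ± 1.10% of counts at P7 and 13.2 ± 1.27% in adults (SD, n = 5 each; two-sided exact permutation p = 0.51, adjusted 0.56).

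Of 38 cytoskeleton genes 13 were higher and 5 lower (13 and 6 adjusted over the list alone; camera adjusted p = 0.0557), among them Coro1a at 2.08, Zyx at 0.73 and Capzb at 0.85. Camera called this list with library size alone (0.0256), with a filter of 10 CPM (0.0174) and without P7 A, E or I or adult A (0.0214 to 0.0483), but not with an estimated correlation (adjusted p = 0.80). The MHC class I list had 4 higher and 2 lower of 18 (5 and 2 adjusted over the list alone), so members moved both ways. H2-K1, a class I heavy chain, fell by 1.15 ± 0.23 (SE), but adult C, at 167 CPM, lay within the P7 range of 140 to 199 CPM. The proteasome activator gene Psme1 rose by 0.79. The proteasome subunit gene Psmb10 rose by 1.77, at low levels of 2.26 CPM at P7 and 0.660 CPM in adults. H2-K1 can share reads with other class I genes, and it passed in 26 of 29 settings. It did not pass with the erythroid covariate, at -1.33 ± 0.55, or the neutrophil covariate, at -0.90 ± 0.54 (SE), or with the 6 libraries of the letters A to C fitted without the block (log2 fold change of H2-K1 -1.08, adjusted p = 0.0646 in edgeR's quasi-likelihood test). Interferon response genes were 7 higher and 4 lower of 28 (7 and 5 adjusted over the list alone), with Ifitm3 up by 1.27, Rsad2 up by 1.90 and Ifi47 at -1.18. Innate immune genes were 3 higher and 3 lower of 18 (4 and 4 adjusted over the list alone), with Rela at 1.08 and Cd84 at -0.65, of which Cd84 did not pass with the GC trend removed (log2 fold change of Cd84 -0.25, adjusted p = 0.14 in edgeR's quasi-likelihood test). In apoptosis genes 1 was higher and 2 lower of 18, also adjusted over the list alone: Bcl2l1, which encodes the survival protein BCL-XL, rose by 0.86, and Bid and Bcl2l11 had log2 fold changes of -1.73 and -1.61.

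Camera with the preset correlation called 5 lists, each higher at P7. Ribosomal protein genes were 36 higher and 0 lower of 77 (38 and 1 adjusted over the list alone), with Rps2 at 2.04 and Rplp0 at 1.17, at a camera adjusted p of 7.62e-09 and an adjusted p = 0.80 with an estimated correlation. Cell cycle genes were 15 higher and 0 lower of 21 (17 and 0 adjusted over the list alone), with Rrm2 at 4.26 and Ccnd3 at 0.71, at a camera adjusted p of 8.20e-07 and an adjusted p = 0.40 with an estimated correlation. Levels of Rrm2 were low, at 2.48 ± 1.01 CPM at P7 and 0.126 ± 0.180 CPM in adults (SD, n = 5 each). Erythroid markers were 9 higher and 0 lower of 22 (10 and 0 adjusted over the list alone), with Fech at 2.04 and Car2 at 2.56, at a camera adjusted p of 5.39e-05 and an adjusted p = 0.40 with an estimated correlation. The globin genes Hbb-bs and Hbb-bt, at log2 fold changes of 0.59 and 0.30, did not pass edgeR's quasi-likelihood test. They held a small part of the globin counts, at 49.8 and 11.3 CPM at P7 and 33.2 and 9.17 CPM in adults. The rest came from Hba-a1 and Hba-a2, near-identical copies whose values are uncertain. The 4 tested globin genes summed to 1555 ± 569 CPM at P7 and 947 ± 500 CPM in adults (SD, n = 5 each, two-sided exact permutation p = 0.095). Glycolysis genes were 5 higher and 0 lower of 17, also adjusted over the list alone, with Aldoc at 2.42 and Gapdh at 0.78, at a camera adjusted p of 0.00792 and an adjusted p = 0.80 with an estimated correlation. Nuclear genes of oxidative phosphorylation were 21 higher and 4 lower of 74 (22 and 4 adjusted over the list alone), with Ndufb7 at 1.21 and Cox5a at -2.95, at a camera adjusted p of 0.00792 and an adjusted p = 0.91 with an estimated correlation. Beside these lists, the share of counts in erythroid markers was 0.331 ± 0.0448% at P7 and 0.225 ± 0.0543% in adults (SD, n = 5 each; two-sided exact permutation p = 0.024, adjusted 0.052). The oxidative phosphorylation list was not called by camera without P7 B (adjusted p = 0.0592) or adult G (0.111). It was also not called with the GC trend removed (0.0586), with the Y-linked covariate (0.0595) or with a filter of 10 CPM (0.0825). The glycolysis list was not called with that filter (0.0825). Median log2 fold changes in these fits were 0.28 to 0.32 against 0.34 for oxidative phosphorylation and 0.56 against 0.60 for glycolysis. Of 100 splits of the 10 libraries into 5 and 5, the real one included, 29 gave at least 5 called lists with the preset correlation, with 11 as the highest of the others.

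**Figure D3:**
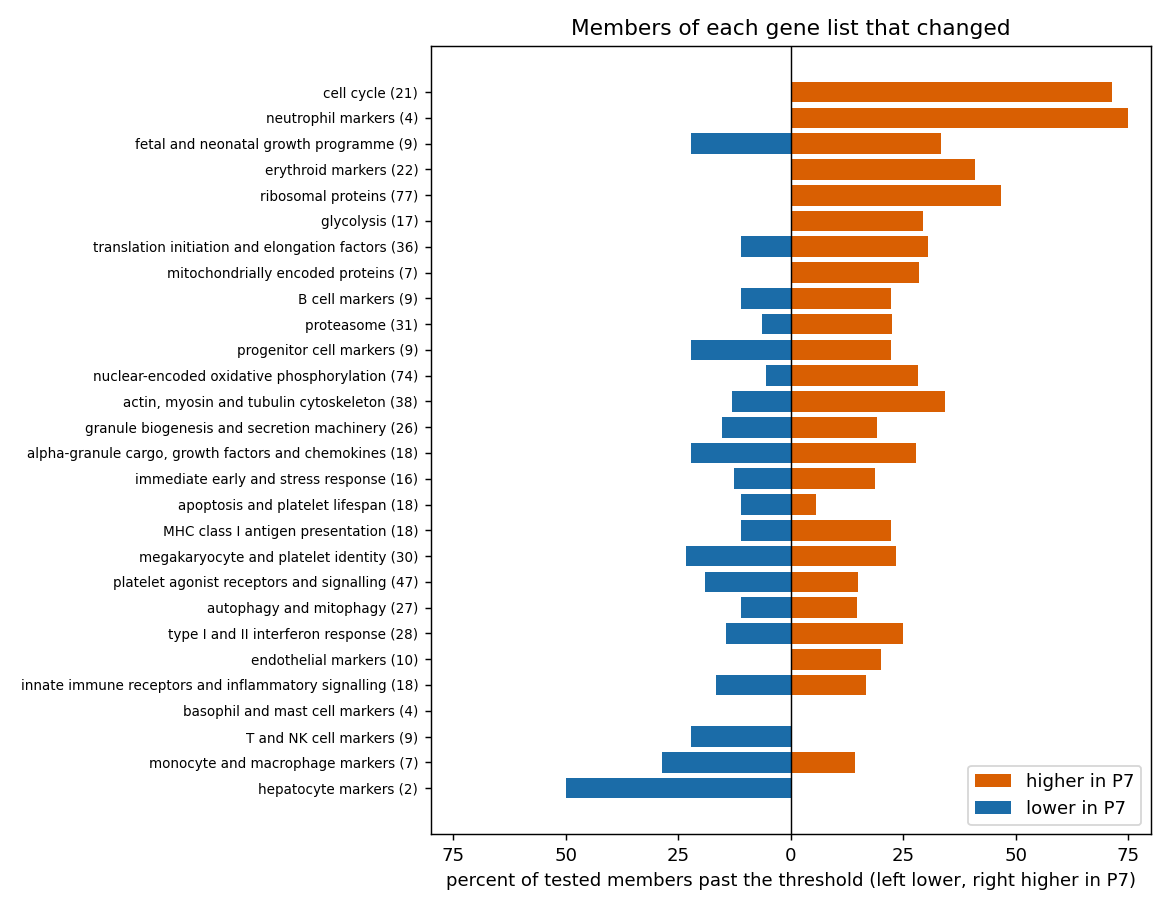
Percent of the tested members of each list that were higher (orange, right) or lower (blue, left) at P7 in edgeR's test, ordered by median log2 fold change, with the number tested in brackets. Cell cycle genes were 15 higher and 0 lower of 21, and ribosomal protein genes 36 higher and 0 lower of 77.

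The other lists had members going both ways or few calls. Fetal and neonatal growth genes were 3 higher and 2 lower of 9 (5 and 2 adjusted over the list alone; camera adjusted p = 0.0604). With the preset correlation this list was called with the replicate letters A to C as a block (0.0246), with the Y-linked covariate (0.0300) and without P7 C, P7 E or adult H (0.0278 to 0.0373), but an estimated correlation gave an adjusted p = 0.80. Its median log2 fold change went from 1.32 to 0.52 without P7 B. H19 had 0 counts in the 5 adult libraries and 3.53 ± 1.08 CPM at P7 (SD, n = 5), at least 126.6-fold higher against 3 counts over the summed adult libraries. Arid3a rose by 2.29, while Hmga2 and Mest had log2 fold changes of -0.94 and -1.06. Proteasome genes were 7 higher and 2 lower of 31 (7 and 3 adjusted over the list alone), with Psmb6 at 1.24. Translation factors were 11 higher and 4 lower of 36, also adjusted over the list alone, with Eif3k at 1.37 and Eif1 at -0.91. Autophagy genes were 4 higher and 3 lower of 27, with Atg9a at 1.87 and Lamp2 at -0.89. Immediate early genes were 3 higher and 2 lower of 16, with Ddit3 at -2.25 and Hsp90ab1 at 0.91. Counts adjusted over the list alone were the same for both. Mitochondrially encoded genes were 2 higher and 0 lower of 7, also adjusted over the list alone, with mt-Co1 at 1.19 (camera adjusted p = 0.128). With the GC trend removed 7 of these were higher and the list was called (camera adjusted p = 2.56e-05), as it was without P7 A (0.0489) or P7 C (0.0278), each with the preset correlation of 0.01. The correlation estimated for these genes was 0.95, with which the list had an adjusted p = 0.91. Median and mean log2 fold change differed in sign for the interferon, innate immune, apoptosis, autophagy, immediate early, progenitor and endothelial lists. For the agonist receptor and alpha-granule lists both were above 0 while camera gave a direction below.

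For the remaining marker lists, those of other cell types, counts adjusted over the list alone equalled those given. Neutrophil markers were 3 higher and 0 lower of 4 tested, with Trem1 at 1.52. Where leaving out P7 A or C or any 1 adult library left enough tested members for camera, this list was called with the preset correlation (adjusted p = 0.00480 to 0.0189). Neutrophil markers held 0.00673 ± 0.00148% of counts at P7 and 0.00218 ± 0.000975% in adults (SD, n = 5 each, two-sided exact permutation p = 0.0079, adjusted 0.029). Most of this share was Trem1, at 53.7 ± 13.4 CPM at P7 and 18.8 ± 9.43 CPM in adults (SD, n = 5 each). The share thus mainly follows Trem1, and 4 of the 27 list genes passed the filter. Monocyte markers were 1 higher and 2 lower of 7, with F10 at 1.71 and Lyz2 at -0.66 (2765 ± 495 CPM at P7 and 4363 ± 1162 CPM in adults), and held 0.306 ± 0.0589% and 0.433 ± 0.110% of counts (exact permutation p = 0.056, adjusted 0.076). B cell markers were 2 higher and 1 lower of 9, with Ighm at 1.47 (share of counts, exact permutation adjusted p = 0.052). T and NK markers were 0 higher and 2 lower of 9, with Nkg7 at -1.38 (share of counts, exact permutation adjusted p = 0.058). Progenitor markers were 2 higher and 2 lower of 9, with Runx1 at -1.53, and endothelial markers 2 higher and 0 lower of 10, with Plvap at 1.43. No call was made among basophil markers, 0 of 4, with Gata2 at -0.22. Hepatocyte markers were 0 higher and 1 lower of 2, with Afp at -1.97.

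Mitochondrially encoded proteins held 0.310 ± 0.0798% of counts at P7 and 0.187 ± 0.0328% in adults, and ribosomal proteins 0.0677 ± 0.0112% and 0.0413 ± 0.00638% (SD, n = 5 each; two-sided exact permutation p = 0.0079, adjusted 0.029, for both). The 20 most abundant genes of a library held 39.7 ± 2.82% and 39.8 ± 2.64% (exact permutation p = 0.94, adjusted 0.94). At equal depth 13860.5 ± 866 genes were detected at P7 and 12758 ± 280.02 in adults (SD, n = 5 each; exact permutation p = 0.040, adjusted 0.062). Without adult A, B or C the neutrophil difference was 0.00439 to 0.00446% of counts, as large in 1 of 126 splits, at an adjusted exact permutation p of 0.0582 to 0.0698. Without any 1 adult library the mitochondrial difference was 0.111 to 0.133%, as large in 3 or 4 splits, at 0.0582 to 0.0873. Without adult A, B, C or G the ribosomal difference was 0.0246 to 0.0282%, as large in 2 splits, at 0.0582 to 0.0698. Thus these calls were lost with differences close to those of all 10 libraries.

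Fold changes followed transcript GC content, with a Spearman's rho of 0.36 across 1973 genes, which are not independent replicates. Genes higher at P7 had a median GC content of 53.3% and genes lower at P7 one of 47.1%. The log2 CPM deviations of each P7 library had a positive rho with GC content, 0.116 to 0.385, and those of each adult library a negative one, -0.366 to -0.184 (two-sided exact permutation p = 0.0079 for the difference of means). As deviations, these values are another view of the fold change trend and not separate support for it. After removal of this trend 2105 genes were called, and 76.5% of the original calls stayed past the threshold in the same direction in edgeR's test.

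**Figure D4:**
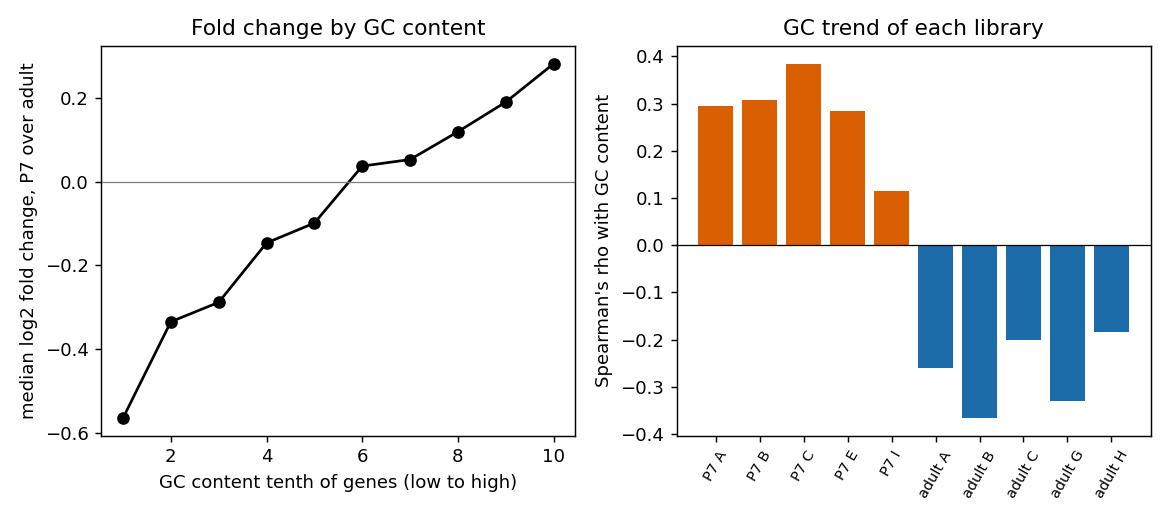
Left, median log2 fold change (P7 over adult) of genes in 10 classes of rising GC content; right, Spearman's rho of each library's log2 CPM deviations with GC content, P7 in orange and adult in blue. The median goes from -0.56 in the lowest class to 0.28 in the highest.

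The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were summed relative to the total counts of each library, without TMM factors. The sums were 7.26 to 11.7 CPM in the 5 P7 libraries and 29.2 and 30.3 CPM in adult A and B. In adult C, G and H these genes had 0 counts. With the Y-linked level as a covariate 2165 genes were called, and 84.6% of the original calls stayed past the threshold in the same direction in edgeR's test.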

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

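The counts of splits were chosen before their results were seen, and the tests on GC content, Y-linked genes, globins, leukocyte genes and RNA of other cells at P7 after the results they bear on. Of 270 sets of 5 libraries, 24 (8.89%) had a library whose gap to the nearest of the others, over the range of the 5, was above 0.71, and chance gives such a gap in about 5% of sets.

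Among abundant genes, adult B stood apart for Tpm2 at 333.8 CPM and Nabp1 at 113 CPM, adult C for Mtmr1 at 115 CPM and Pla2g4a at 224 CPM, and adult H for Ptp4a3 at 18.4 CPM. P7 I was low for Ptp4a3 at 31.1 CPM. P7 I was high for B2m at 2103 CPM, against 937 to 1220 CPM in the other P7 libraries. Adult A was high for Itga2b at 22349 CPM, Ifi47 at 74.3 CPM and Plvap at 67.4 CPM. Adult G was high for Psmd11 at 244.8 CPM, where P7 E was low at 104.8 CPM. Adult H was low for Ap3b1 at 14.1 CPM and high for Il7 at 19.05 CPM and Spi1 at 2.75 CPM. P7 C was high for Aldoc at 19.3 CPM, P7 E for Il1rap at 0.880 CPM, adult B for Car2 at 3.01 CPM and adult C for Eif3k at 5.80 CPM. Adult G was high for Cdh5 at 2.14 CPM, Rps19 at 1.93 CPM and the neutrophil marker share at 0.00390% of counts. P7 I was low for Rrm2 at 0.685 CPM, and adult H had the fewest genes at equal depth, 12263.

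The ages differed in 2272 genes, and 1 of 100 splits of the libraries, the real one, gave as many, with 6 genes as the highest of the others. This argues against a random split of these 10 libraries as the source of the count. Each other split mixed the ages within its groups, so few calls were likely there. Chance differences between few animals are not excluded, since the labels do not say whether libraries came from separate animals, pools or repeated draws. A GC trend or different Y-linked levels as the whole cause are argued against by the 76.5% and 84.6% of calls that stayed with each removed, though part of the lost calls may come from either. For the 5 called gene lists chance cannot be excluded, since 29 of 100 splits gave as many and the highest of the others was 11. Red cells or reticulocytes in the P7 preparations could underlie the erythroid list, and stay open. The gain of the globins less that of 18 other erythroid genes was 279.4 ± 339 CPM (SE), which cannot decide it. Most globin counts were those of Hba-a1 and Hba-a2, whose values are uncertain. Red cells or neutrophils at P7 as the whole cause are argued against for the lower genes. Added RNA lowers no gene relative to platelet RNA, taken here as the summed identity genes, of which 7 of 30 were higher and 7 lower. With libraries scaled to this sum 811 of 8198 genes were lower, against 4 changed in 1 direction as the highest of the other splits. For the higher genes the covariate fits cannot decide, since age explained 82.1% and 81.8% of the erythroid and neutrophil marker levels. In these fits 1.24% and 12.1% of the higher genes stayed called, and such cells cannot be told apart from age, itself open. The marker shares differed by 0.106% (erythroid) and 0.00455% (neutrophil) of counts, but other RNA of such cells was not measured.

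B2m and H2-K1 were lower at P7, while H2-D1, a more abundant class I heavy chain chosen after its values were seen, was not called (log2 fold change of H2-D1 -0.84 ± 0.68, SE, adjusted p = 0.41 in edgeR's test) and ran from 227 to 1636 CPM at P7 and from 439 to 3047 CPM in adults. With the GC trend removed the log2 fold change of B2m was -1.75 ± 0.19 (SE), and with the Y-linked level as a covariate it was -2.21 ± 0.24, with both genes past the threshold each time, which argues against either as the whole cause. Over 29 tested leukocyte genes the median log2 fold change was 0.32 (SD 1.07), so these genes as a set were not higher in adults. Medians were 1.48 for neutrophil and 0.37 for B cell markers, but -0.66 for monocyte and -0.56 for T and NK markers. The most abundant, Lyz2, was itself 1598 CPM higher in adults. The others summed to 172 CPM in adults against a B2m difference of 4466 CPM. How much B2m such cells would carry was not measured, so monocytes or T and NK cells in the adult preparations stay open. With the erythroid covariate B2m went from -2.19 ± 0.22 to -1.44 ± 0.42 and H2-K1 from -1.15 ± 0.23 to -1.33 ± 0.55 (SE), and neither passed. In that fit both SE were larger, the change of B2m was smaller, and age explained 82.1% of the covariate. Which of these cost the calls was not tested. With libraries scaled to the summed identity genes B2m was at -2.05 ± 0.25 and H2-K1 at -1.01 ± 0.23 (SE), both past the threshold. If that sum stands for platelet RNA, this argues against red cells or neutrophils at P7 as the whole cause. Of the 30 identity genes 7 were higher and 7 lower at P7, which limits that reading. Identity shares of counts were alike at both ages (12.7% and 13.2%), so this fit lay close to the main fit. Lower B2m and H2-K1 in platelets of P7 mice, not extended here to other class I genes, may follow from age, a hypothesis found and tested on the same libraries, and differences in strain or class I genotype and reads shared between class I copies were not tested and stay open.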

How the results depend on the processing

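Removal of the GC trend and the Y-linked covariate were chosen after the data were seen, and the other settings before. Against 2272 called genes (1132 higher, 1140 lower; 739 and 627 at least 2-fold), a filter of 10 CPM in 5 libraries gave 1209 (568, 641; 212 and 224) because it tested 2797 genes. An adjusted p under 0.01 gave 1228 (582, 646; 460 higher at least 2-fold), and glmTreat against 1.5-fold gave 883 (439, 444; 434 higher at least 2-fold). The erythroid covariate gave 29 (14, 15; 14 and 15) and the neutrophil covariate 313 (141, 172; 139 and 172), where age explained 82.1% and 81.8% of the covariate's variance. The letters A to C are shared between the ages, but deviations of libraries with the same letter correlated at -0.18, 0.10 and -0.07, so they were not taken as pairs. The replicate block gave 1416 genes (660, 756) and the same 6 libraries without it 1886. With the block 5 lists were called, with the fetal and neonatal growth list in place of oxidative phosphorylation (camera adjusted p = 0.0956). Leaving out each library gave 1843 (without P7 C) to 2394 (without P7 I) genes. The 10 CPM filter called 3 lists, ribosomal, erythroid and newly cytoskeleton, with too few cell cycle genes left to test. An estimated correlation called 0, and 4 (without P7 B) to 8 (without P7 A or C) were called with a library left out. Fry called 9 (8 higher, 1 lower), without oxidative phosphorylation (0.0508) and newly with cytoskeleton, fetal and neonatal growth, proteasome, translation factors and, lower, T and NK markers. Removal of the GC trend and the Y-linked covariate each called 5, with the mitochondrially encoded and the fetal and neonatal growth list in place of oxidative phosphorylation. RLE, library size, upper-quartile, DESeq2, limma-voom, equal depth and the removed gene sets kept the count within 1.5 times. Library size alone moved the median log2 fold change from 0.05 to 0.11, upper-quartile factors also to 0.11 and no filter to 0.24. With the erythroid covariate the sign changed for the log2 fold change of Mavs (-0.21), the log2 fold change of Bcl2l11 (0.67), the log2 fold change of Cd163 (0.10), the log2 fold change of Itga2b (-0.28) and the log2 fold change of F2rl3 (-0.44), none past the threshold there. With the Y-linked covariate the log2 fold change of Ddx3y was 1.38, which is that covariate's own gene. Of 3429 results of 124 named genes, 3123 stayed on their side of the threshold, 298 no longer passed, 2 passed newly and 6, those just given, changed sign. The 3123 include 33 whose sign changed while past the threshold in neither fit, as it did for 35 list results. Without mitochondrially encoded genes the erythroid share differed by 0.110% and the B cell share by 0.00191%, and without erythroid genes the B cell share by 0.00186%, each then past the threshold in the exact test. With a library left out, differences in shares ran from 0.0927 to 0.121% (erythroid, past the threshold without adult H), 0.00421 to 0.00498% (neutrophil, lost without adult A, B or C). They ran from -0.160 to -0.0880% (monocyte, past it without adult G), 0.00133 to 0.00219% (B cell, past it without adult H), -0.00266 to -0.00137% (T and NK, past it without adult H). Further ranges were 0.0939 to 0.142% (mitochondrial, lost without any 1 adult library) and 0.0238 to 0.0308% (ribosomal, lost without adult A, B, C or G), and genes at equal depth from 922 to 1454.5 (past it without P7 B). Apart from the number of genes tested and the overlap of covariates with age, the cause was not tested. The planned covariate from the ratio of Y-linked to Xist counts was not run, since Xist had 0 counts in the 10 libraries. Depth limits genes under about 0.154 CPM, which a count of 0 allows in the shallowest library.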

Other observations

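The tests in this part were chosen after the pattern was seen. Some abundant genes were on in some libraries and nearly off in others of the same age. Genes ranked above for their change with age were among the most variable within an age. Ttc9 was at 0.960 CPM in P7 E and 192 to 550 CPM in the other P7 libraries. Ociad2 ran from 1.51 to 24.6 CPM in adults and Pamr1 from 0.310 to 16.8 CPM at P7. Rubcn was at 3.01 CPM in adult A and 169.6 to 356 CPM in the other adult libraries, and Iqcg, 3 protein-coding genes away, at 0.0477 CPM in adult A and 16.2 to 64.4 CPM in the others. Ceacam2 was at 0.459 CPM in adult H and 74.2 to 95.2 CPM in the other adult libraries, and Ints13 and Fgfr1op2 were also lowest in adult H among adults, at 10.1 and 64.5 CPM. Of 2025 genes, 44 had an SD above 1 on the log2 scale among adult libraries and 24 among P7 libraries.

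Inherited differences between animals, linked along chromosomes, may underlie such genes, but the test did not settle it. Neighbouring pairs without overlap and without related copies were counted among the 50, 100 or 200 most variable genes, up to 5 or 10 protein-coding genes apart in the RefSeq GRCm38 order, against 10000 random draws. In 4 of these 6 settings the share of draws with as many pairs was 0.0001 (the smallest that can be given) to 0.012, and with 200 genes it was 0.31 and 0.45. A first version that kept related copies found 13 pairs against 3.15 in random draws, and was replaced because related copies can share reads; without them the same setting gave 8 pairs, and the rule for reading the shares was also changed after they were seen. Reads shared between adjacent genes stay open as well, since pairs with another gene between them had shares of 0.0006 to 0.92, under 0.05 in 1 of 6 settings. Strain and litter of the animals would be needed to test inherited differences.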
